A study of Mus musculus with 6 samples.

How the data were processed

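RNA from primary sorted bone marrow cells of mice with leukemia was extracted with a column kit for small samples, labelled with a GeneChip wild-type terminal kit and measured on 1 Affymetrix array per sample, per the labels' protocols. The labels call the cells osteoblastic, while the titles call them stromal. The submitters' processing notes name limma and lumi, with no version, step or order. How the authors corrected background, summarised probe sets and normalized the arrays is not given in the sources used here. The deposited value table holds intensity values on a linear scale, as judged from its values, which are decimals from 2.71 to 8583. The median, quantiles and SD differ between arrays, so the deposited probe set values do not share a common distribution. Whether the arrays were normalized at an earlier step cannot be judged from these values. The log2 SD was 1.77, 1.83 and 1.75 on CML 1, 2 and 3 and 1.90, 1.88 and 1.91 on AML 1, 2 and 3. No detection p-value was used here, so dim probe sets were not set against a background.

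The groups were taken from the titles, 3 CML and 3 AML arrays. The source names give CML for all 6 samples and so disagree with the titles of the AML samples. The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined, except where said otherwise.

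Of 39721 probe sets, 23521 were paired with 1 gene symbol in the platform annotation, 1814 with several and 14386 with none. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which held 23328 of the probe sets with 1 symbol and missed 193. It changed 0 symbols. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. Probe sets with several symbols or none were left out of the comparison by gene. The probe set with the highest mean stood for each of the 1082 genes with more than 1, which left 22180 genes. Where named genes had a second probe set that disagreed, its value is given.

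Log2 of the deposited intensity, with a floor at 1 that 0 values reached, was fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, without trend, robust option, covariate or filter, which left 4 residual degrees of freedom per gene before moderation. Tests were two-sided, changes are AML minus CML, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors are the moderated ones of limma. The 29 lists held 420 different genes, of which 382 were measured by a probe set with 1 symbol and 38 were not analysed here. Each list was tested against the other genes with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way, or in either direction, without comparing them with other genes. The score of a list on an array is the mean log2 value of its genes minus the mean over the 6 arrays.

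Named genes were the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap. Where fewer fell, the next by unadjusted p filled the place and is said not to have passed. Predicted genes, small RNA genes with Mir, Snor or n-R symbols and olfactory or vomeronasal receptors were passed over by name, among them 15 calls higher and 7 lower in AML. Up to 4 genes past the threshold were named from each list, or the 2 with the lowest unadjusted p where none passed. Col1a1, Bglap, Sp7, Cxcl12, Kitl, Ptprc and Pecam1 were named whatever their values. This gave 83 genes, of which 33 passed. Further genes were named after their values were seen, and the text says where.

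The alternatives were quantile normalization, median centring, cyclic loess, the upper 50% and upper 70% of genes by mean level, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust options, array weights, TREAT against a log2 change of 0.5, a log2 change of at least 1 as a further threshold, a replicate block and leaving out each array. Covariates for the Xist level and for pan-haematopoietic genes were added after the data were seen.

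The steps were tested on simulated data of 22180 genes for AML against CML with 50 changed genes per size. Limma called 34.0% at an absolute log2 change of 1, 68.0% at 2, 90.0% at 3 and 84.0% at 4, with 4 false calls. Camera called the planted list and 0 others, in simulated genes without correlation. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.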

Results

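Gene expression was measured on 6 microarrays, 3 from mice with chronic myeloid leukemia (CML) and 3 from mice with acute myeloid leukemia (AML). The RNA came from sorted osteoblastic cells of the bone marrow of mice carrying a Col2.3 GFP reporter, in which a fragment of the Col1a1 promoter labels cells of the bone-forming lineage with green fluorescent protein. The comparison asks which genes differ between the marrow stromal cells of the leukemias. The titles and the series design assign 3 arrays to each leukemia, whereas the source names give CML for all 6 samples. The titles were followed, so each direction below rests on them. Every array held 39721 probe sets. The median intensity was 19.1, 18.6 and 20.4 on CML 1, 2 and 3, and 17.2, 17.8 and 17.4 on AML 1, 2 and 3. No read depth applies to arrays, and their number limits the precision. Nothing in the labels says that the samples came from separate mice, so p-values measure the spread between these samples, which may be technical.

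The AML arrays resembled one another more than the CML arrays did. The Pearson correlation of log2 values across probe sets, which are not independent replicates, ran from 0.955 to 0.966 within AML and from 0.906 to 0.931 within CML. It ran from 0.892 to 0.935 between the groups. The first principal component held 41.1% of the variance and placed the CML arrays between -78.2 and -42.3 and the AML arrays between 46.4 and 77.0. The second held 25% and spread the CML arrays from -71.5 to 78.4.

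The largest named rises in AML included several genes known from myeloid cells. Clec12a (probe set 17463509, chromosome 6), an inhibitory C-type lectin receptor of myeloid cells, was 25.1-fold higher, with log2 intensities of 9.92 ± 0.56 in AML and 5.27 ± 1.14 in CML (SD, n = 3 each; limma adjusted p = 0.0266). With 1 array left out its log2 change ran from 4.24 to 5.30, against 4.65 as fitted, and it passed in 3 of these fits. Elane (probe set 17235011, chromosome 10), the neutrophil elastase of primary granules, was 14.4-fold higher, at 11.04 ± 0.65 against 7.19 ± 0.32 (limma adjusted p = 0.0151). Meis1 (probe set 17260815, chromosome 11), a homeobox cofactor of HOXA9 in haematopoietic progenitors and leukemia, was 13.2-fold higher, at 8.21 ± 0.13 against 4.49 ± 0.37, and had the lowest adjusted p of all genes (limma adjusted p = 0.0136). The other 9 of the 12 largest named rises were Clec4b2, Ms4a6c, Fcnb, Atp8b4, B4galt6, Olfm4, Ms4a3, Aoah and Ly86, with log2 changes between 4.45 for Clec4b2 and 3.49 for Ly86. Among them, Fcnb encodes ficolin B, Olfm4 encodes a granule protein of neutrophil precursors, Aoah encodes the enzyme that deacylates bacterial lipopolysaccharide, and Ly86 encodes the partner of the receptor CD180.

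Among genes past the adjusted threshold, 18 fell. Rnu3a, a U3 small nucleolar RNA gene, fell by 3.00 ± 0.43 on the log2 scale (SE; limma adjusted p = 0.0325). Rsad2 and Usp18, both induced by type I interferon, fell by 2.76 ± 0.48 and 1.47 ± 0.19 (SE; limma adjusted p = 0.0491 and 0.0298). The interferon gene Ifna1 fell by 0.90 ± 0.15 (SE; limma adjusted p = 0.0441). Mical3, Apol10a, Zfp521, Dst, Krtap5-2, Fn3k and Lce3a also fell, with log2 changes between -1.43 for Mical3 and -0.88 for Lce3a. With 1 array left out, Mical3 passed in 2 fits, Apol10a, Zfp521 and Krtap5-2 in 1 each and Dst, Fn3k and Lce3a in 0. Mical3 passed under all 3 other scalings and each of the others under 1. Lce3a was dim, with means of 3.94 in CML and 3.06 in AML, and Dst had a mean of 3.75 in AML. The array medians were 4.11 to 4.35. Zfp521 encodes a zinc finger protein of progenitor cells and osteoblasts, and Dst encodes the cytoskeletal linker dystonin. Gcn1, next by its unadjusted p, stood at -0.80 and did not pass (limma adjusted p = 0.0509); its other probe set gave -0.04.

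**Figure D1:**
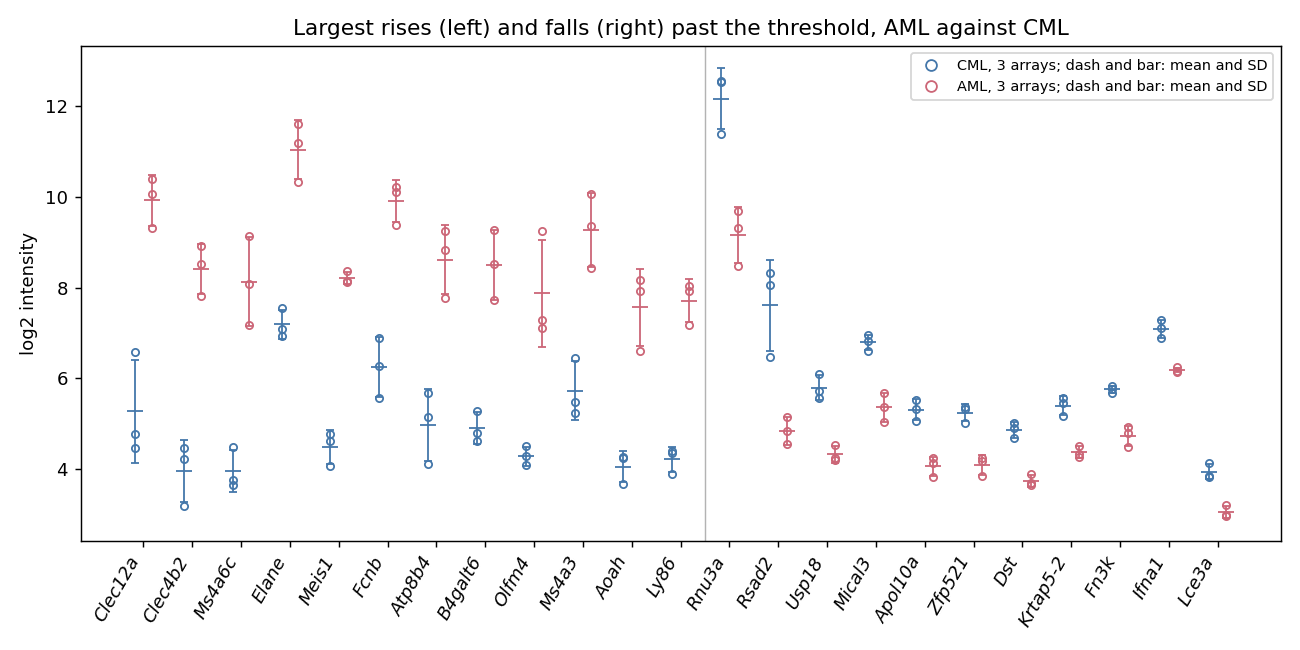
Log2 intensity (y axis) of the 12 largest named rises and the 11 named falls past the threshold, for the 3 CML arrays (blue) and the 3 AML arrays (red); circles are arrays, dashes are means and bars are SD. The arrays of the groups do not overlap for any of these genes, and the difference of means is largest for Clec12a, at 5.27 in CML and 9.92 in AML.

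In all, 423 of 22180 genes passed an adjusted p of 0.05 in limma, 405 higher and 18 lower in AML. The balance was more even at an unadjusted p under 0.05, where 2784 of 4777 genes were higher and 1993 lower. Of the 423 genes, 379 differed by at least 2-fold, 139 by at least 4-fold and 33 by at least 8-fold. The groups did not overlap for any of the 423 genes, and they did not overlap for 31.3% of all genes, where chance gives 10%. The median change of all genes was -0.11 on the log2 scale, and median centring of the arrays moved it to 0.04. The count was 0 without CML 3, without AML 1 and without AML 2, with 3533, 3048 and 3750 genes at an unadjusted p under 0.05 in limma, and it was 279 without AML 3. It was 93 after quantile normalization, 64 after cyclic loess and 896 after median centring, with 93.6%, 95.3% and 97.5% of the genes higher in AML.

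Among the haematopoietic lists, 4 passed as higher in AML: primary granules and myeloid progenitors, stem and progenitor cells, granulocytes, and monocytes and macrophages. These are camera calls with the preset correlation, and none of the 4 held with an estimated one (adjusted p = 0.426 for the first 2 and adjusted p = 0.843 for the last 2 with an estimated correlation). Erythroid, B lineage and T and NK genes were mostly lower by value. Of 10 genes of primary granules and myeloid progenitors, 8 rose, among them Elane, Fcnb, Ms4a3 and Ctsg (log2 changes 3.85, 3.65, 3.55 and 3.17), and adjusted over the list alone all 10 did. The list's median change was 2.89 (camera adjusted p = 1.0e-11 with the preset correlation; adjusted p = 0.426 with an estimated correlation). Of 14 genes of haematopoietic stem and progenitor cells, 4 rose, and 9 did when adjusted over the list alone. These 4 were Meis1, Hoxa9, Mecom and Kit. Hoxa9 changed by 3.09 ± 0.40, Mecom by 1.99 ± 0.13 and Kit, the receptor of stem cell factor, by 1.80 ± 0.21 (SE). The list's median was 1.32 (camera adjusted p = 5.2e-07; adjusted p = 0.426 with an estimated correlation). Mecom's other probe set gave 0.48.

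The granulocyte and monocyte lists passed with the preset correlation at smaller medians, and neither did with an estimated one (adjusted p = 0.843 for both with an estimated correlation). Of 14 granulocyte genes, Chil3, a chitinase-like secreted protein, rose by 2.37 ± 0.20 (SE), and 3 passed when adjusted over the list alone. The list's median was 0.79 (camera adjusted p = 0.00377), and its call ended without CML 2 (median 0.36, camera adjusted p = 0.216), after cyclic loess (0.162) and among the upper 50% of genes by mean level (0.151). Without CML 3 its median was 1.19 (camera adjusted p = 4.9e-05). Of 16 monocyte and macrophage genes, Cd68 rose by 2.80 ± 0.49 and Ccr2, a chemokine receptor of inflammatory monocytes, by 2.23 ± 0.34 (SE). Adjusted over the list alone, 5 of them rose and 1 fell. The list's median was 0.74 (camera adjusted p = 0.0303), and its call ended under all 3 other scalings, with camera adjusted p from 0.0554 to 0.0930, without CML 1 (0.0557), CML 2 (0.0607) or AML 1 (0.129), and among the upper 50% and upper 70% of genes by mean level (0.114 and 0.113). Its median was 1.56 in the upper 50% and 1.17 without AML 3, where it passed (camera adjusted p = 0.00271).

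Pan-haematopoietic genes were also higher in AML by value, and 2 of 17 passed in limma. A list of 18 genes of blood cells, held by no other list, was written after the lists had been tested and before its own values were seen. Some of these genes, such as Tyrobp and Fcer1g, are mainly of myeloid and NK cells, so the list does not weigh every blood lineage alike. All 17 of its measured genes were higher in AML by value, with a median change of 1.47, and Vav1 and Ptpn6 passed in limma. Ptprc, the pan-leukocyte marker CD45, was 2.36 ± 0.80 higher by value (SE) and did not pass (limma adjusted p = 0.176). It ranged from 4.96 on CML 2 to 8.27 on CML 1, and from 8.17 to 9.30 on the AML arrays. With 1 array left out its log2 change ran from 1.61 to 3.26, and it passed in limma in 1 of these fits. The array score of the 17 genes did not overlap between the groups, from -1.48 to -0.006 in CML and from 0.42 to 0.98 in AML. A covariate made of it therefore moves largely with the leukemia, and a fit with it cannot separate the 2. With the mean level of the 17 genes as a covariate, a setting chosen after the data were seen, 5 genes passed in limma and 3 of the 4 lists no longer passed in camera. The fourth, primary granules and myeloid progenitors, still passed with the preset correlation, with its median going from 2.89 to 1.99 (camera adjusted p = 1.3e-05). Without the covariate this list did not pass with an estimated correlation (camera adjusted p = 0.426). The stem and progenitor median went from 1.32 to 0.29 (camera adjusted p = 0.155), the monocyte and macrophage median from 0.74 to 0.095 (0.629) and the granulocyte median from 0.79 to -0.37 (0.200).

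Genes of the labelled lineage itself were lower in AML by value, with none past the threshold. All 18 measured genes of osteoblasts and bone matrix were lower by value, with a median of -0.88 (camera adjusted p = 0.0135; adjusted p = 0.843 with an estimated correlation). None passed in limma, over all genes or adjusted over the list alone. Col1a1 (probe set 17255260, chromosome 11), the main collagen of bone and the source of the reporter's promoter, was at 8.59 ± 1.31 in AML and 10.30 ± 1.62 in CML (SD, n = 3 each; limma adjusted p = 0.316). Sp7, the osteoblast transcription factor osterix, was at 5.26 ± 0.57 against 6.65 ± 1.75, and Bglap, which encodes osteocalcin, at 4.20 ± 0.79 against 5.37 ± 1.48 (limma adjusted p = 0.343 and 0.374). Bglap was at 7.04 on CML 3 and dim on the other arrays, from 3.31 to 4.84 against array medians of 4.11 to 4.35. With 1 array left out its log2 change ran from -1.72 to -0.33. The list's call ended without CML 3 (median -0.34, camera adjusted p = 0.386) and without AML 3 (median -0.60, camera adjusted p = 0.0956). The median moved away from 0 without AML 2 (-1.35, camera adjusted p = 0.00213), without CML 2 (-1.40, 0.000119) and with the pan-haematopoietic covariate (-1.74, 0.00237). CML 3 lay 1.75 above the mean of the 6 arrays on this list, and AML 3 lay at -0.98.

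The stromal lists beside bone did not pass as fitted. Those of mesenchymal progenitors, chondrocytes and extracellular matrix passed as lower in AML among the upper 50% of genes by mean level (camera adjusted p = 0.0461 for each), and adipocyte genes passed as higher without AML 3 (0.0437). None of these 4 lists passed with an estimated correlation (adjusted p = 0.843 for 3 of them and 0.933 for matrix). Without CML 3 the mesenchymal median was -0.006 and the matrix median -0.08. The adipocyte median was 0.40 without AML 3 and turned to -0.08 without AML 2. Haematopoietic niche factors had a median of -0.03 and a mean of 0.004 over 16 genes, 8 higher and 8 lower (camera adjusted p = 0.983). Cxcl12, which retains haematopoietic stem cells in the marrow, was 0.92 ± 0.43 higher by value and Kitl, which encodes stem cell factor, differed by 0.005 ± 0.22 (SE; limma adjusted p = 0.267 and 0.990). Kitl was dim, with means of 3.865 in CML and 3.87 in AML against array medians of 4.11 to 4.35. Its small difference may therefore reflect a lack of signal. Angpt1 was 1.63 ± 0.37 higher by value and did not pass (SE; limma adjusted p = 0.0855), and its other probe set gave 0.23. Il7 was at -0.39. The medians were -0.24 for mesenchymal progenitors and perivascular stroma (camera adjusted p = 0.274), 0.11 for adipocytes (0.228), -0.35 for chondrocytes (0.163), -0.46 for extracellular matrix and fibrosis (0.371) and -0.24 for endothelium (0.279). Adjusted over the list alone, 1 gene each passed in the adipocyte and matrix lists, both higher in AML. The adipocyte gene was Cebpa, at 0.96 ± 0.22 (SE; limma adjusted p = 0.0839 over all genes). Cebpa is also a member of the primary granule and myeloid progenitor list, so its rise is not particular to adipocytes. Among matrix genes, Fn1 was 2.78 ± 0.60 higher by value and did not pass (SE; limma adjusted p = 0.0742). Pecam1, an endothelial and haematopoietic adhesion molecule, was 1.20 ± 0.53 higher by value (SE; limma adjusted p = 0.244).

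The type I interferon list was lower in AML with the preset correlation (camera adjusted p = 0.00229; adjusted p = 0.426 with an estimated correlation). Of 19 measured genes of the type I interferon response, Rsad2 and Usp18 fell, and 8 fell when adjusted over the list alone. By value 16 were lower and 3 higher, with a median of -0.50. All 3 CML arrays lay above the list's mean and all 3 AML arrays below it, at 0.45 ± 0.18 and -0.45 ± 0.15 (SD, n = 3 each). In limma, Rsad2 passed in 1 of the fits with 1 array left out and Usp18 in 2, and each passed under 1 of the 3 other scalings. The list passed in camera with the preset correlation without each array in turn and under the 3 other scalings. Its median was -0.79 with the pan-haematopoietic covariate (camera adjusted p = 0.00571) and -1.18 among the upper 50% of genes by mean level (2.4e-06). Genes of the interferon gamma response and antigen presentation had a median of -0.08 (camera adjusted p = 0.706; adjusted p = 0.933 with an estimated correlation; 0.0413 with the pan-haematopoietic covariate, at -0.42), and Cxcl9 and Irgm1, their leading members, stood at -0.72 and -0.70 without passing.

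**Figure D2:**
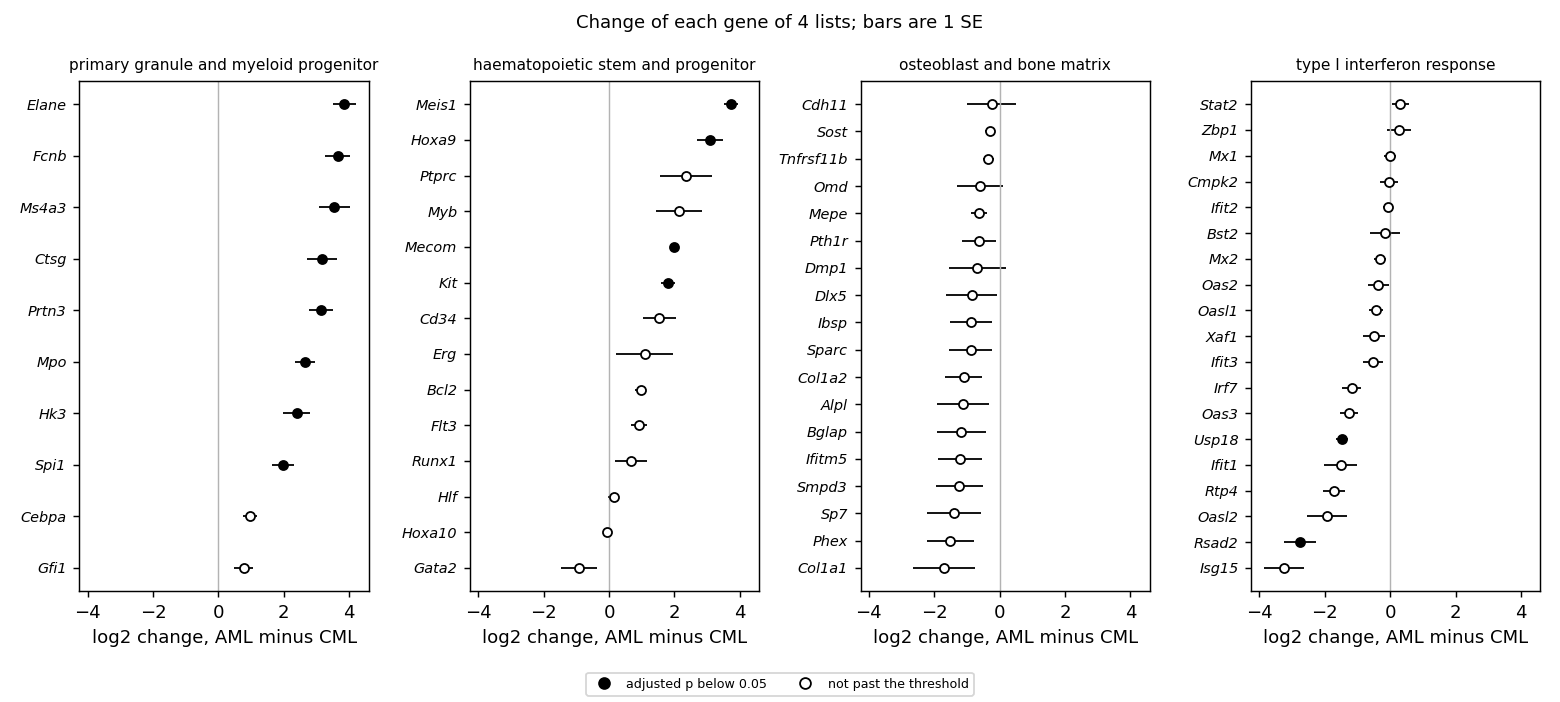
Log2 change in AML minus CML (x axis) of each measured gene of 4 lists; points are limma estimates, bars are 1 SE, and filled points passed an adjusted p of 0.05. All 10 primary granule genes lie above 0 and 8 are filled, all 18 bone genes lie below 0 and none is filled, and 16 of 19 type I interferon genes lie below 0.

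The 2 lists for energy metabolism were also higher in AML with the preset correlation, with few single genes past the threshold. Neither call held with an estimated one (adjusted p = 0.843 for oxidative phosphorylation and adjusted p = 0.530 for hypoxia and glycolysis with an estimated correlation). Of 16 genes of oxidative phosphorylation, Ndufb5, a subunit of respiratory complex I, rose by 0.95 ± 0.14 (SE). The median was 0.44 (camera adjusted p = 0.00229), and the call ended after quantile normalization (median 0.26, camera adjusted p = 0.0564), after cyclic loess (0.13, 0.502) and among the upper 50% of genes by mean level (0.187). The median was 0.28 without CML 3 (camera adjusted p = 0.0495) and 0.90 with the pan-haematopoietic covariate (2.9e-05). Of 13 genes of hypoxia and glycolysis none passed over all genes, 6 were higher when adjusted over the list alone, and the median was 0.53 (camera adjusted p = 0.00996). Pgk1, a glycolytic kinase, was 1.57 ± 0.33 higher by value, and Hif1a 1.04 ± 0.23, with 0.51 at its other probe set. The call of this list held at a median of 0.27 after quantile normalization (camera adjusted p = 0.0449) and ended after cyclic loess (0.33, 0.0742) and among the upper 50% and upper 70% of genes by mean level (0.114 and 0.0695).

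Among the other signalling lists, single genes passed while no list passed in camera as fitted. Notch2, a Notch receptor, rose by 1.55 ± 0.20, and Id2, an inhibitor of basic helix-loop-helix factors, by 1.75 ± 0.23 (SE; limma adjusted p = 0.0298 for both). The Notch list had a median of -0.21 (camera adjusted p = 0.903). The BMP and TGF-beta list had a median of -0.20 and a mean of 0.14 (0.747), and 2 of its genes passed when adjusted over the list alone. Tested with fry for changes in either direction, the Notch, BMP and TGF-beta, and Wnt lists passed (adjusted p = 9.9e-05, 9.8e-06 and 0.0290), which does not compare them with other genes. For Wnt targets and regulators the median was -0.28 (0.225), with Dkk1 at -0.86 and Sfrp4 at 0.70. Inflammatory cytokines and chemokines had a median of -0.23 (0.820; adjusted p = 0.972 with an estimated correlation), with Osm at -1.45 and Il1a at -0.64. That median ran from 0.22 without CML 1 (camera adjusted p = 0.537) to -0.51 without AML 1 (0.203) and -0.91 with the pan-haematopoietic covariate, where alone the list passed (0.000804). Stress response genes had a median of -0.16 and a mean of -0.21, while their camera direction was up (0.950). Dnajb9 stood at 1.45 and Trib3 at -1.73, and 1 of these genes passed when adjusted over the list alone. Immediate early genes had a median of 0.41 (0.132; adjusted p = 0.843 with an estimated correlation) and passed without CML 1 (0.73, 0.00789), without AML 3 (0.0350) and with the Xist level as a covariate (0.00319), also chosen after the data were seen. The median was 0.025 without AML 1 (camera adjusted p = 0.652) and turned to -0.81 with the pan-haematopoietic covariate (0.0628). Cell cycle genes had a median of 0.24 (camera adjusted p = 0.0550; adjusted p = 0.866 with an estimated correlation), which turned to -0.12 after cyclic loess (0.268). They passed without CML 2 (0.00215), AML 1 (0.0276) or AML 2 (0.00330) and with the pan-haematopoietic covariate (1.0e-06), where the median was highest at 0.78.

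Erythroid and B lineage genes were lower in AML by value, and their calls changed with the setting. Erythroid genes had a median of -1.85 (camera adjusted p = 0.0653), running from -1.005 without AML 1 to -2.78 without AML 3. They passed as lower in AML after quantile normalization (0.00635), median centring (0.00620) and cyclic loess (0.00140), in the upper 50% and upper 70% of genes by mean level (0.00161 and 0.0250), with the Xist covariate (0.00958) and without CML 1 (0.0202) or AML 3 (0.000224). The estimated correlation gave an adjusted p = 0.843, and the pan-haematopoietic covariate turned the median to 1.13 (camera adjusted p = 0.103). The arrays spread widely, with an array score of -2.85 on AML 1 and 1.09 on AML 3; Epb42 and Tfrc were at -2.62 and -1.58. B lineage genes had a median of -1.47 (camera adjusted p = 0.116; adjusted p = 0.843 with an estimated correlation). They passed as lower after median centring (0.0188), in the upper 50% and upper 70% of genes by mean level (0.00617 and 0.0471), with the pan-haematopoietic covariate (-5.01, 6.5e-09) and without CML 2 (0.00215) or AML 2 (0.0430), while the median was -0.63 without CML 1 (camera adjusted p = 0.561). CML 1 stood at 2.32 while CML 2 stood at -0.94; Cd79a and Blnk were at -2.68 and -2.06. Megakaryocyte genes had a median of 0.84 (camera adjusted p = 0.228; adjusted p = 0.894 with an estimated correlation), which turned to -0.03 without AML 3 (0.983) and passed at 1.56 without AML 1 (0.00724) and at 2.34 with the pan-haematopoietic covariate (0.00220). Their array score was 2.05 on AML 3, where Ppbp and Pf4 reached log2 intensities of 9.91 and 10.16. T and NK genes had a median of -0.47 (camera adjusted p = 0.163; adjusted p = 0.843 with an estimated correlation; 0.0101 with the pan-haematopoietic covariate, at -0.62), although Nkg7 was 1.68 higher by value, and 1 gene passed when adjusted over the list alone. The T and NK median ran from -0.12 without CML 1 to -0.59 without CML 2. Osteoclast genes had a median of -0.38 (0.747), with Nfatc1 at 1.18, and 1 gene passed when adjusted over the list alone. Skeletal muscle genes had a median of -0.19 (0.724) and Schwann and glial genes one of -0.19 (0.558).

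**Figure D3:**
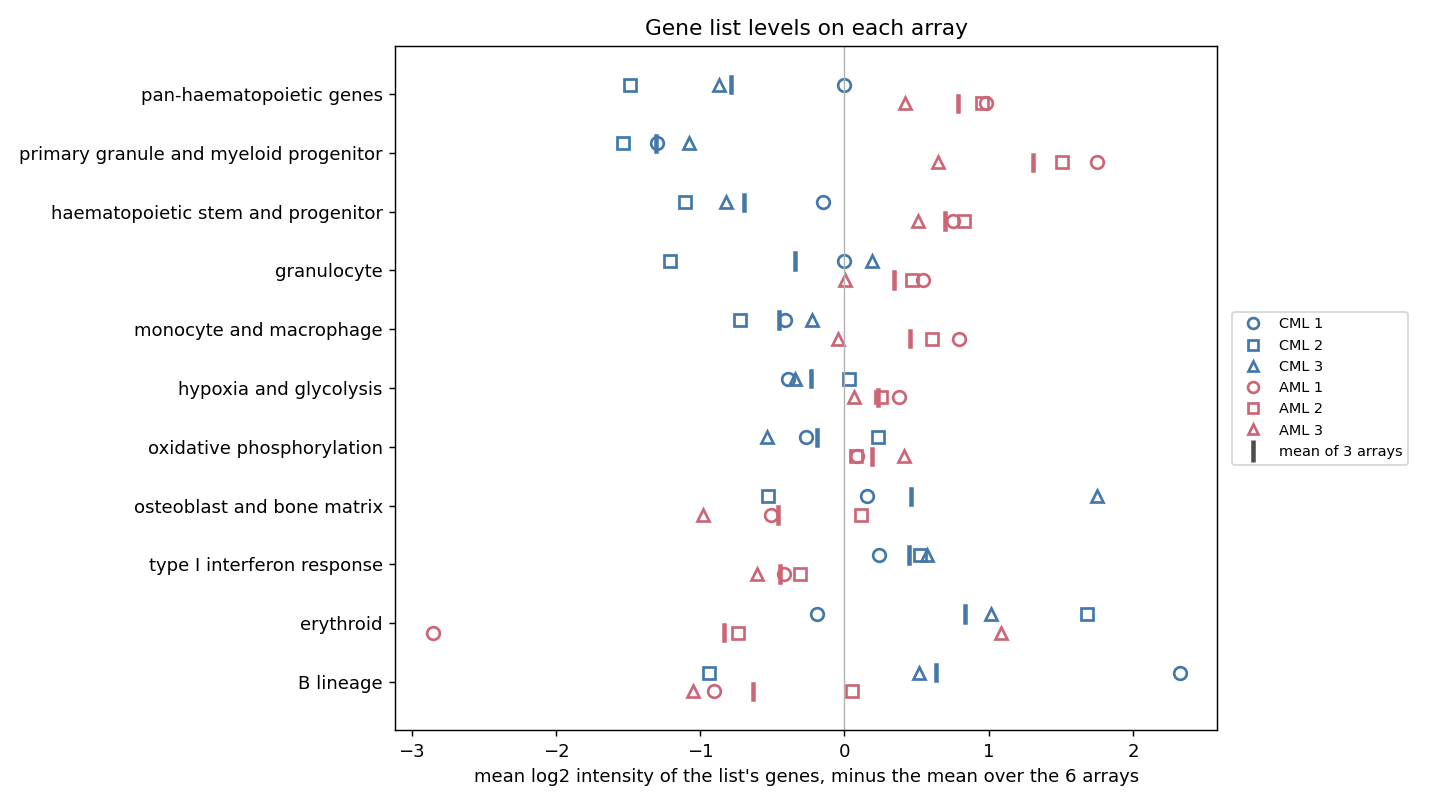
Mean log2 intensity of the genes of 10 lists and of the pan-haematopoietic genes on each array, minus the mean over the 6 arrays (x axis); symbols are arrays, CML in blue and AML in red, and vertical dashes are means of 3 arrays. Primary granule genes lie apart in the groups, bone genes spread from -0.53 to 1.75 within CML, and erythroid genes spread from -2.85 to 1.09 within AML.

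Across the 29 lists, 20 of 382 measured genes passed in limma, 18 higher and 2 lower. With the preset correlation 8 lists passed in camera, 6 higher and 2 lower, and with an estimated correlation 0 did (lowest adjusted p = 0.426; 3 lists at an unadjusted p under 0.05). Other splits of the 6 arrays into groups of 3 gave between 6 and 14 lists with the preset correlation. A directional rotation test, fry, called 3 lists: primary granules (adjusted p = 0.0287), stem and progenitor cells (0.0279) and type I interferon (0.0436). In either direction fry called 13 lists, among them osteoclasts (adjusted p = 9.8e-06), T and NK cells (0.00431), and niche factors and adipocytes (0.0290 for both). The count of 20 genes fell to 0 without CML 3, AML 1 or AML 2.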

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

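The test of all haematopoietic kinds moving alike and the test of stromal dilution were chosen only after the results were seen. The judgement of the former was also changed after its values were seen, so that 1 list moving apart was enough. Before the change both the B lineage and the erythroid list had to move apart. The erythroid gap to the pan-haematopoietic change, 3.25 ± 1.63 (SE), was within 2 SE, so the earlier judgement would not have been met.

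Probe sets left out of the comparison by gene also held signal between the groups. With every probe set tested on its own in limma, 59 of the 14386 probe sets without a symbol passed, 53 higher and 6 lower in AML. Of the 1814 probe sets with several symbols, 8 passed, 7 higher and 1 lower. The largest of these, shared by Mira and Hoxa7, rose by 2.91 ± 0.24 on the log2 scale (SE; limma adjusted p = 0.0227), while the probe set of Hoxa7 alone gave 0.58.

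Primary granule and myeloid progenitor genes had a median change of 2.89. The tables argue against scaling as the whole cause, since the smaller median after quantile normalization or cyclic loess was 2.55. They also argue against a single array as the source of the direction, since the median stayed between 2.61 and 3.20 with 1 array left out. The highest camera adjusted p was then 9.8e-09 with the preset correlation, a setting that also called many lists in other splits of the arrays. With all arrays and an estimated correlation the list did not pass (camera adjusted p = 0.426). B lineage genes alone argue against haematopoietic RNA of all kinds alike, since they lay 2.84 ± 0.59 below the pan-haematopoietic change, 2.39 ± 0.51 without CML 1 and never under 3.05 SE with 1 array left out, whereas the erythroid gap of 3.25 ± 1.63 (SE) was within 2 SE. The pan-haematopoietic list holds genes mainly of myeloid and NK cells, such as Tyrobp at 2.60. Part of the B lineage gap may therefore set myeloid against B lineage genes. A larger share of haematopoietic RNA of some kind in the sorted AML samples met the rule written for it before the values were seen. The pan-haematopoietic median was 1.47 and all 17 measured genes were higher, so this explanation stays open with values on its side. A GFP sort would be meant to remove such cells, yet Ptprc was between 8.17 and 9.30 on the AML arrays and between 4.96 and 8.27 on the CML arrays. With the pan-haematopoietic level as a covariate the list still passed at a median of 1.99 (camera adjusted p = 1.3e-05 with the preset correlation). That level lay apart between the groups, so the fit with it cannot weigh this explanation. A difference between the leukemias in the labelled cells themselves stays open too and was not tested.

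Type I interferon genes had a median of -0.50. The smaller change after quantile normalization or cyclic loess was -0.56 (-0.36 after median centring, which raised the median of all genes to 0.04), which argues against scaling as the whole cause. With 1 array left out the median ran from -0.34 without CML 1 to -0.70 without AML 1, which argues against a single array as the source of the direction. The highest camera adjusted p was then 0.010 with the preset correlation. With all arrays and an estimated correlation the list did not pass (camera adjusted p = 0.426). With the pan-haematopoietic level as a covariate the change of the list's mean was -0.72 ± 0.29, against -0.89 ± 0.14 without it (SE), while the median went the other way, to -0.79 (camera adjusted p = 0.00571). The rule written before the values were seen judged the mean alone. The mean's change with the covariate lay within 1 SE of the rule's limit, so whether a different share of haematopoietic RNA plays a part stays open. The mean and the median also moved in opposite directions. The pan-haematopoietic level also lay apart between the groups, so a fit with it could not separate it from the leukemia. A difference in interferon signalling between the leukemias stays open as well and was not tested.

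Bone matrix genes had a median of -0.88. A single array could account for the call, since the highest camera adjusted p with 1 array left out was 0.386, without CML 3, and the call also ended without AML 3 (0.0956). Dilution of all stromal RNA by other RNA cannot be told apart from a loss of bone genes, because the median of mesenchymal progenitor genes was -0.24 and that of matrix genes -0.46, between no change and a matching one. Without CML 3 the mesenchymal median was -0.006, the matrix median -0.08 and the bone median -0.34, so the mesenchymal and matrix values hang on CML 3 and leave dilution open. With the pan-haematopoietic covariate the bone median was -1.74 (camera adjusted p = 0.00237). That covariate lay apart between the groups, so the fit with it does not weigh dilution. A difference between the leukemias in bone formation stays open and was not tested.

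The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For genes past the threshold 1 of the 10 splits gave as many, the real one, with 423 genes against 0 in the highest other. For single genes of the lists it was also 1, with 20 against 0. For lists past the threshold in camera, 8 of the 10 splits gave as many, with 8 lists in the real split and 14 in the highest other. The count of 8 lists with the preset correlation therefore does not set the leukemias apart from other groupings. Among these 8 lists the estimated correlation ran from 0.034 for type I interferon to 0.802 for bone, above the preset 0.01. The cause of the many calls was not tested.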

How the results depend on the processing

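The Xist and pan-haematopoietic covariates, and the alternatives for list genes and list medians, were chosen after the data were seen. Where no construction is named, the cause of a shift was not tested.

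The count of 423 genes moved to 93 with quantile normalization, 64 with cyclic loess, 896 with median centring, 272 with every probe set on its own (more tests), 639 with array weights, 42 with TREAT (a stricter hypothesis), 51 with the Xist covariate and 5 with the pan-haematopoietic covariate, the last 2 with fewer degrees of freedom. Of the 93 and 64 genes, 91 and 63 were among the 423, and of the 5 genes 1 was. The pan-haematopoietic level did not overlap between the groups, so the fit with it could not separate it from the leukemia. Leaving out 1 array gave 0 to 438 genes, with 0 without CML 3, AML 1 or AML 2 (lowest limma adjusted p 0.0645, 0.0649 and 0.110). The 20 genes of the lists became 9 with quantile normalization, 33 with median centring, 4 with cyclic loess, 5 with TREAT, 5 with the Xist covariate and 0 with the pan-haematopoietic covariate, and 0 to 20 with 1 array left out. The 8 lists in camera became 5 with cyclic loess and 0 with an estimated correlation, while fry called 3 by direction and 13 in either direction; the other settings gave 7 to 11 lists.

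The replicate numbers did not pair the arrays: the correlation of same-numbered deviations was 0.20, -0.22 and -0.17, and CML 1 alone correlated best with its own number. With the replicate block 0 genes passed in limma (3711 at an unadjusted p under 0.05), 0 genes of the lists passed, and 9 lists passed in camera with the preset correlation, the erythroid list among them (adjusted p 0.00550). Without the block the erythroid list did not pass with an estimated correlation (camera adjusted p = 0.843).

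Among 1390 values of the 83 named genes under the alternatives, 1087 kept direction and side of the threshold, 277 kept direction and no longer passed, 14 newly passed and 12 changed sign, 0 of these in genes past the threshold. With the pan-haematopoietic covariate the granulocyte median turned to -0.37, and the changes became 0.98 for Epb42, 1.13 for Tfrc, 0.29 for Trib3, -0.19 for Klf2, -0.30 for Kitl, -1.08 for Ptprc and -0.77 for Pecam1. With 1 array left out, Mbp ranged from -0.60 to 0.20 and changed sign without CML 3, and Kitl ranged from -0.16 to 0.22 and changed sign without CML 1, CML 2, AML 1 or AML 2. The primary granule and type I interferon lists passed in camera under every setting run except the estimated correlation. Signal over background was not measured here, so its limit on dim genes is unknown.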

Other observations

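The tests on symbol families and the description of lysosomal and oxidase genes were chosen only after the results were seen, while the test on the other Hoxa genes was written before their values were seen.

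Lysosomal genes and the phagocyte NADPH oxidase, which makes superoxide in myeloid cells, were among the genes higher in AML. Both lists were written after the genes past the threshold had been read, and partly from them, so an enrichment test on them would be circular and their counts are descriptions. Of 38 measured genes of lysosomal enzymes and membrane proteins, 10 rose in limma and 0 fell. The largest of these rises were 3.29 ± 0.39 for Hexa, a subunit of beta-hexosaminidase, 2.44 ± 0.22 for Gnptab, which tags enzymes for the lysosome, and 2.14 ± 0.34 for Scarb2 (SE; limma adjusted p = 0.0248, 0.0151 and 0.0407). All 28 others were higher by value as deposited, and the median of the 38 was 0.90; after quantile normalization or cyclic loess 37 of the 38 were higher. Of 5 measured oxidase genes, Cyba, Ncf1 and Ncf4 rose, by 2.32, 2.20 and 2.03, and Cybb and Rac2 were higher by value without passing. Rac2 is also among the pan-haematopoietic genes, which had a median change of 1.47. Before these lists, 327 families of genes with a shared symbol stem were tested for enrichment among the rises with Fisher's exact test, and none passed (lowest adjusted p = 0.292, for 3 of 11 annexin genes).

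Of 14 measured granulocyte genes 11 were higher and 3 lower in AML by value, and Chil3 rose. Cebpe, a transcription factor of granule formation, stood at 2.42 ± 0.45 and Camp at 1.24 ± 0.42 without passing (SE; limma adjusted p = 0.0543 and 0.173). Itgb2l, Csf3r, Lcn2, Ngp, Ly6g, S100a9 and Ltf were at 1.65, 1.12, 1.03, 0.90, 0.68, 0.58 and 0.30, none of them past the threshold. S100a8, abundant in mature neutrophils, stood at 0.13 ± 0.27, Mmp8 at -0.54 ± 0.45, Cxcr2 at -0.68 ± 0.73 and Retnlg at -1.66 ± 0.52 (SE; limma adjusted p = 0.778, 0.475, 0.568 and 0.152). Their spread was looked at only after the values were seen, and no difference between these genes was tested.

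A hypothesis that the Hoxa cluster was active as a whole was tested on the other Hoxa genes, with Hoxa10 left out because its value had been seen. Hoxa9 rose by 3.09 ± 0.40 and Hoxa5 by 1.84 ± 0.22 (SE; limma adjusted p = 0.0290 and 0.0248). The median of the 7 other genes was 0.49, from -0.25 for Hoxa13 to 1.84 for Hoxa5, and 1 of the 7 passed. The test left the question open, since the genes ranged from no change to a clear rise. A probe set shared by Mira and Hoxa7 lay outside this test. It rose by 2.91 when every probe set was tested (limma adjusted p = 0.0227). Hoxa10 stood at -0.05 as deposited. After each of the 3 other scalings 7 of the 8 Hoxa genes beside Hoxa9 were higher in AML, against 6 as deposited.

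Globin probe sets, each shared by several genes, were low on AML 1. The brightest beta-globin probe set had a log2 intensity of 8.94 there and between 12.1 and 12.6 on the other arrays, and an alpha-globin probe set had 8.34 there and between 11.8 and 12.5 on the others. Xist, expressed from the inactive X chromosome of females, had log2 intensities of 5.75, 6.57 and 9.88 on CML 1, 2 and 3 and 5.83, 9.70 and 9.47 on AML 1, 2 and 3, so high and low arrays occurred in both groups. The Y-linked gene Eif2s3y was at 5.10, 7.76 and 4.43 on the CML arrays and 6.55, 5.22 and 5.72 on the AML arrays. It did not simply mirror Xist, since CML 1 was low for Xist without being high for Eif2s3y. The arrays were therefore not sorted by sex.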
